A study of Mus musculus with 8 samples.

How the data were processed

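RNA from MC3T3 cells, a mouse osteoblast line derived from calvarial bone, was compared on 8 spotted cDNA arrays with 2 colours each. Every array carried RNA of cells exposed to oscillatory fluid flow in one dye and RNA of untreated cells in the other. Per the labels, 4 arrays belong to the 30 min time and 4 to the 1 h time, with the RNA of the flow cells in Cy5 on replicates 1 and 3 and in Cy3 on replicates 2 and 4 of each time. Cells were grown in medium with 10% serum and exposed to a sinusoidal flow at 1 Hz with a peak shear stress of about 10 dyn per cm2 at 80 to 90% confluency, per the labels. The labels give 30 min and 1 h both as the duration of flow and as the time of harvest after stimulation, so the 2 readings are left open here. They do not say whether the arrays of a time came from separate cultures, whether replicates of opposite dye are dye swaps of the same extracts, or whether the arrays share untreated RNA. The p-values therefore measure only the spread between these samples, which may be technical, and a test of the ratio against 0 leaves out the untreated cells' own spread if their RNA was shared.

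The authors deposited the output of image analysis for each array, with 1 entry for each of 43008 spots. Per the file headers, the values used here are the mean spot intensity and the median local background intensity of each channel, without normalization. The software's signal-to-noise score for each channel and spot, its spot flag and the percent of saturated pixels were also taken as deposited. The deposited log2 ratio of red over green is named as normalized in the file headers, but its normalized and raw channel columns are equal, so no normalization had been applied. The authors' value table of the whole series holds intensity values that equal the sum of both channels' background-subtracted median intensities on 100% of spots of every array, with a median per array of 339, 235, 326 and 460.5 at 30 min and of 1595, 856, 590 and 749 at 1 h. It is on a linear scale, not centred, and holds no ratio, so it has no direction and could not serve as an alternative. The scanner, the image software and its version are not given in the sources used here.

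Of the spots, 38953 carried cDNA clones, 3072 were controls and 983 were empty. A gene symbol was given in the files for 26465 cDNA spots; 17877 of these symbols stood as such in the RefSeq gene table of GRCm38.p6, and 25828 did after old symbols had been updated through its synonyms. The other symbols were kept as the files give them. No coordinates are given, since the files name no genome build.

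Background was corrected with normexp at an offset of 50, and each array was normalized by loess, with weight 0 for control spots, empty spots and spots with the software's bad flag of -100. The log2 ratios of the arrays with flow RNA in Cy3 were turned, so that every value reads flow over untreated. Bad spots and control spots were left out. Spots with the software's not found flag of -50, between 16690 and 24773 cDNA spots per array, were kept where they passed the filter below. So were spots marked as failed. Saturated spots, with more than 50% of their pixels saturated in a channel, were kept, and there were only 2. A spot was kept if its signal-to-noise score was above 3 in at least 1 channel on at least 4 of the 8 arrays. The kept spots of a clone were averaged, so its dim spots that did not pass were left out. A clone also had to be measured on at least 3 arrays of each time. Of several clones of a gene the one with the highest mean log2 intensity was tested. This left 8887 genes, of which 8366 were measured on all arrays. The design written beforehand had assumed scanner flags for signals well above background and for outlier spots; these arrays do not have those flags, and the signal-to-noise score and the bad flag were used in their place.

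All comparisons came from 1 linear model in limma 3.58.1 (R 4.3.3; files read with version 1.17.8 of the package data.table) fitted to all 8 arrays, with a mean for each time and a term for the dye orientation, followed by eBayes. Tests were two-sided and adjusted by Benjamini-Hochberg over the 8887 genes, with calls at an adjusted p under 0.05. The 4 comparisons were flow against untreated at 30 min, the same at 1 h, the difference between these times and the mean of both times. Every adjusted p given for a gene is from this limma model unless another is named. Folds and log2 values are of flow over untreated. The mean ± SD of a gene is over the arrays of a time.

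Gene lists were tested with camera in limma with a preset correlation of 0.01 between genes. Its p-values were adjusted over the lists with at least 3 genes measured on all arrays. Camera with an estimated correlation and fry were the alternatives. An estimated correlation leaves camera only the few residual degrees of freedom of the arrays, which by itself raises its p-values. There were 27 lists, written from textbook knowledge, which include markers of 5 other cell types. Genes were named by a fixed rule: for each time the 8 highest and the 8 lowest called genes with the same sign on all arrays of that time, for the difference the 5 highest and the 5 lowest, filled up to 5 by the smallest p where fewer passed, up to 4 genes with the smallest p of each list that passed, and 12 genes chosen for the topic whatever their values. Of the genes this rule takes, 2 are not reported here. Genes named outside this rule are given as chosen after their values were seen.

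The model was tested on simulated data with the real arrays' residual spread, in which 100 of the 8887 genes were changed by 1 and another 100 by 2 log2 units at 30 min. It recovered 77% of changes of 1 log2 unit and 98% of changes of 2 log2 units at 30 min, with 11 false calls among 186. A shift of 0.5 log2 units given to the heat shock list was called by camera at an adjusted p of 4.32e-22, with 0 other lists called.

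The samples, groups, model, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were other background corrections and normalizations, filters on dim spots, treatment of bad spots, handling of several clones of a gene, the dye term, the arrays in the fit, the variance model, the replicate number as a block, averaged pairs of replicates of opposite dye, other thresholds, an unmoderated test per gene, and leaving out each array. A further 6 were chosen after seeing the data. A block for slide or scan batch was not run, since the files give neither. The number of arrays limits the precision, and the signal over background of the red channel limits it further: 42.2 to 45.7% of cDNA spots were above background in red on 6 arrays.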

Results

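Gene expression was measured in MC3T3 osteoblasts exposed to oscillatory fluid flow, on 8 arrays that each compared flow with untreated cells: 4 at 30 min and 4 at 1 h. Of the cDNA spots, between 57.7 and 67.9% were above background in the green channel. In the red channel this share lay between 42.2 and 45.7% on 6 arrays, and at 69.2% and 64.0% on replicates 1 and 2 of 1 h, where the median red background was 364 and 128 intensity units against 463 to 817 elsewhere. After every ratio was turned to flow over untreated, the arrays of the same dye orientation correlated at r = 0.16 to 0.67 across genes, all 12 pairs being above 0, whereas the 16 pairs of opposite orientation ranged from -0.61 to 0.59 with a median of -0.15. Genes are not independent replicates in these correlations. The model held a term for the dye, and each time held both orientations equally.

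The first comparison addressed which genes responded 30 min into or after flow. Hmox1, which encodes the haem-degrading enzyme haem oxygenase, was 15.3-fold higher with flow (log2 3.94 ± 0.49, SD, n = 4; adjusted p = 0.000464). The transcription factor genes Csrnp1 (5.77-fold, log2 2.53 ± 0.16) and Atf3 (4.97-fold, log2 2.31 ± 0.25) rose, as did Plk2, a polo-like kinase gene (log2 2.29 ± 0.40), and Prl2a1, a gene of the prolactin family (log2 2.92 ± 0.46), whose untreated channel was above background on 2 of the 4 arrays. Gadd45g, a growth arrest and stress gene, rose by 2.06 ± 0.78, Epcam, a cell adhesion gene, by 1.97 ± 0.79, and Mt2, a metallothionein gene, by 1.87 ± 0.40 on the log2 scale. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, was 2.61-fold higher (log2 1.38 ± 0.29, adjusted p = 0.00674), with a log2 ratio of 1.06 on another bright clone and of -0.04 on a dim one.

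Among the genes that fell at 30 min, Igfbp4 and Igfbp5, which bind insulin-like growth factors, were 2.39-fold and 2.22-fold lower (log2 -1.26 ± 0.33 and -1.15 ± 0.19, n = 4). Irs1, an adaptor of the insulin receptor, had a log2 ratio of -1.17 ± 0.69, and Pik3ip1, an inhibitor of PI3-kinase, of -1.09 ± 0.14. The largest decrease was that of Zfp503, a zinc finger gene (log2 -1.43 ± 0.16). Ahr, the aryl hydrocarbon receptor, fell to -1.26 ± 0.18, Pycr1, an enzyme of proline synthesis, to -1.07 ± 0.41, and Dhrs3, a retinal reductase, to -0.97 ± 0.33. The call of Igfbp4 rests on its brightest clone, since 2 others gave 0.19 and -0.04; dim clones of Zfp503 (0.26), Epcam (0.10) and Hmox1 (0.61) also gave values nearer to 0 or of the other sign. As a mean over its clones Pik3ip1 stood at -0.35, Igfbp4 at -0.37, Zfp503 at -0.58, Pycr1 at -0.69 and Ptgs2 at 0.80, none of which passed, and Hmox1 at 2.27, which did. Dhrs3 stood at -0.17 when only spots above background in both channels on all arrays were used, which moved the choice to another clone. With no filter on dim spots, further spots of the tested clones entered their averages. Plk2 then stood at 1.14 and still passed, whereas Epcam stood at 0.99 and did not. Another clone of Atf3 gave 1.27, with its 2 spots at 0.35 and 2.18. Over all 30 called genes with further clones, 44 of 53 other clones had the sign of the tested clone.

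In total 51 of 8887 genes passed at 30 min, 36 higher and 15 lower with flow, and all 51 had the same sign on every array measured at 30 min. Of these, 28 were more than 2-fold higher and 7 more than 2-fold lower. The unadjusted p was under 0.05 for 1109 genes, where 444.35 would be by chance. With median centring of each array in place of loess, 12 genes passed, 12 higher and 0 lower, and the unmoderated test per gene called 0 genes. Without replicate 1, 2, 3 or 4 of 30 min the number was 8, 20, 17 or 7, and without replicate 3 of 1 h it was 33.

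**Figure D1:**
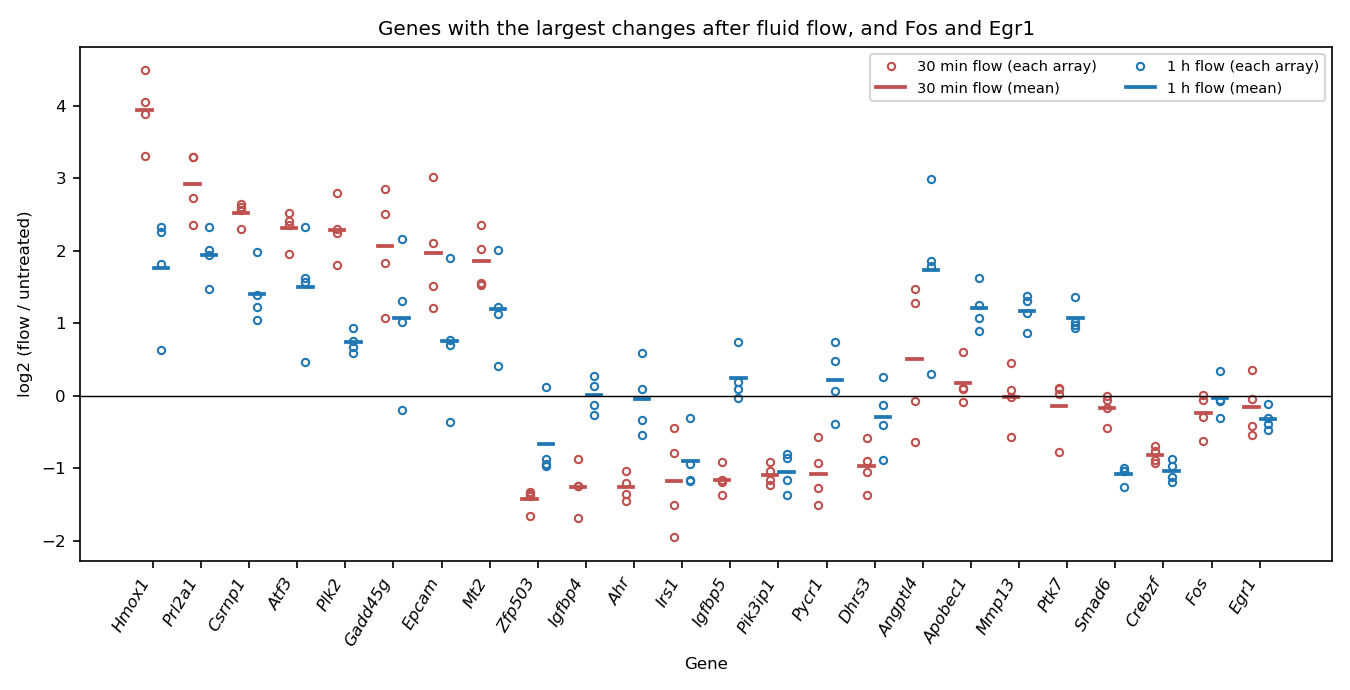
The log2 ratio of flow over untreated (vertical axis) on each array (circles) and the mean (bars) at 30 min and 1 h, for the genes with the largest called changes at either time and for Fos and Egr1. Hmox1 lies at 3.94 on average at 30 min and at 1.76 at 1 h, and Fos and Egr1 lie near 0 at 30 min.

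Among the gene lists, immediate early transcription factors rose at 30 min: 6 of 23 measured genes rose and 17 did not pass, and 12 rose when adjusted over the list alone (camera adjusted p = 1.89e-07, median log2 0.52). Besides Csrnp1 and Atf3 these included Fosl1, an AP-1 subunit (1.76 ± 0.63), and Nr4a1, an orphan nuclear receptor (1.25 ± 0.28). The best known members did not pass: Fos had a log2 ratio of -0.24 (95% interval -0.55 to 0.07, adjusted p = 0.533) and Egr1 of -0.16 (95% interval -0.49 to 0.17, adjusted p = 0.749). Of 20 genes of MAPK phosphatases and signalling feedback, 4 rose, 1 fell and 15 did not pass, against 10 and 2 adjusted over the list alone (camera adjusted p = 3.77e-05). Gadd45b (1.36 ± 0.41), the MAPK phosphatase gene Dusp1 (1.20 ± 0.19) and Zfp36, whose product speeds the decay of mRNAs (1.15 ± 0.37), were among the genes that rose. The 1 that fell was Socs3, a feedback inhibitor of cytokine signalling (-0.93 ± 0.33), which is named after its value was seen. With no filter on dim spots Dusp1 stood at 0.60 and did not pass, and with the scanner's log ratio it stood at 1.90, Atf3 at 3.51 and Osgin1 at 2.54, none of which passed.

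The oxidative stress, heat shock and cholesterol synthesis lists also passed at 30 min. In the oxidative stress list 3 of 20 genes rose and 7 did adjusted over the list alone (camera adjusted p = 1.94e-06). With Hmox1 and Mt2 the third was Osgin1, an oxidative stress induced growth inhibitor (1.60 ± 0.72), while the autophagy receptor gene Sqstm1 stood at 0.74 ± 0.52 (adjusted p = 0.0663). In the heat shock list 2 of 18 genes rose, Hspa1a (1.57 ± 0.53) and Hspb8 (0.83 ± 0.43), and 3 did adjusted over the list alone (camera adjusted p = 0.00216). With an estimated correlation, which was -0.0088, that list gave an adjusted p = 0.0655. The co-chaperone gene Dnajb1 stood at 0.82 ± 0.57 (adjusted p = 0.101) and Hspa1b at 0.66 ± 0.79 (adjusted p = 0.291). In the cholesterol synthesis list 1 of 14 genes, Msmo1 (0.81 ± 0.14), a sterol oxidase gene, rose and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.94e-06, median 0.44). Insig1, a sterol sensor, lay on the same side (1.06 ± 0.62, adjusted p = 0.0925), whereas Fdft1, the squalene synthase gene, lay at -1.09 ± 0.55 (adjusted p = 0.102), with its 2 spots at -2.07 and -0.12. As a mean over its clones Msmo1 stood at 0.37 and did not pass.

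With a correlation between genes estimated from the arrays, 4 of these 5 lists passed, the immediate early and oxidative stress lists at an adjusted p = 0.0313 and the MAPK feedback and cholesterol lists at 0.0356. By fry, which asks whether a list's genes move one way and not whether they differ from other genes, 6 lists passed. When only spots above background in both channels on all arrays were used, MAPK feedback and heat shock both stood at a camera adjusted p = 0.0511.

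The other lists did not pass at 30 min. The nearest were BMP and TGF-beta pathway genes, in which 2 of 18 genes rose and 5 did adjusted over the list alone, and CREB, calcium and NFAT targets, in which 1 of 15 rose and 2 did adjusted over the list alone (both adjusted p = 0.0637). The 2 BMP genes, seen after the test, were Id1, an inhibitor of differentiation (1.71 ± 0.99), and Klf10 (1.18). Prostaglandin genes gave an adjusted p of 0.553, with Ptgs2 the 1 called of 10, and 1 adjusted over the list alone. Osteoblast markers (14 genes, median -0.03, adjusted p = 0.590), Wnt pathway genes (0.270), YAP/TAZ targets (0.853), actin cytoskeleton genes (0.369), cytokines (0.369), growth factors (0.579), matrix genes (0.368) and mechanosensing channels and integrins (0.807) did not pass. Neither did the lists for hypoxia (0.369), the cell cycle (0.349), interferon (0.560), the circadian clock (0.791), ribosomal proteins (0.369) and the unfolded protein response (0.560, with 4 genes higher and 3 lower adjusted over the list alone). The markers of skeletal muscle (0.853), chondrocytes (0.560), macrophages (0.790) and endothelium (0.791) did not pass, and the 3 measured adipocyte genes, too few for a test, had a median of -0.13. The median, the mean and the test differed in sign for YAP/TAZ targets, mechanosensing, skeletal muscle and endothelial genes, and the adipocyte genes had a mean of 0.06.

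The other genes chosen for the topic did not pass at 30 min. Spp1, or osteopontin, stood at -0.07 ± 0.13, Col1a1, type I collagen, at 0.45 ± 0.35 (95% interval 0.10 to 0.80, adjusted p = 0.279), Ccn1 at -0.05 ± 0.61 and Ccn2 at 0.38 ± 0.71, the last 2 being matricellular genes, and Gapdh at 0.07 ± 0.65. Actb, or beta-actin, stood at 0.13 ± 0.32, but at -0.60 when Aquantile scaling moved the choice to another clone and at -0.20 as a mean of clones. Under median centring the values for Spp1 and Ccn1 were 0.06 and 0.02. Il6 and Bglap1, on 4 spots and 1 spot that were not well above background, and Runx2, which no spot named, were not tested.

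The comparison at 1 h asked for genes changed at the later time. Prl2a1 (3.83-fold, log2 1.94 ± 0.35, n = 4), Atf3 (2.83-fold, with an SD of 0.77 on the log2 scale) and Csrnp1 (2.66-fold, log2 1.41 ± 0.41) were again higher with flow. Angptl4, an inhibitor of lipoprotein lipase, rose 3.33-fold (log2 1.74 ± 1.10), with each of its channels above background on only 3 arrays. Apobec1, an RNA-editing cytidine deaminase, rose by 1.21 ± 0.31, and Mmp13, a collagenase of bone remodelling, by 1.17 ± 0.23 on the log2 scale, with 1.30 on another clone and -0.58 on a dim one. Mt2 (1.19 ± 0.65) and Ptk7, a pseudokinase of planar cell polarity (1.07 ± 0.20), also rose. Smad6, an inhibitor of BMP signalling, was 2.12-fold lower (log2 -1.08 ± 0.12), and Pik3ip1 (-1.05 ± 0.27) and the leucine zipper gene Crebzf (-1.03 ± 0.15) fell. Dlx5, a homeobox factor of osteoblast differentiation, stood at -0.95 ± 0.12 (adjusted p = 0.0577) and Trim59 at -0.77 ± 0.09 (adjusted p = 0.0594), neither of which passed.

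Of 8887 genes, 18 passed at 1 h, 15 higher and 3 lower, all with the same sign on every array of that time; adjusted p-values lay at 0.0231 or above, and the unadjusted p was under 0.05 for 1101 genes. With a normexp offset of 16 there were 7, 4 higher and 3 lower, and limma called 0 genes when fitted to the arrays of 1 h alone. Without replicate 1, 2, 3 or 4 of 1 h, or replicate 1 or 3 of 30 min, limma called 0 genes, and without replicate 2 or 4 of 30 min it called 4 and 1, while the unmoderated test per gene on all arrays called 1. The 2 arrays with a low red background belonged to this time, and with either kind of array alone at 1 h, which leaves fewer arrays in the fit, limma called 0. The log2 ratios of the 2 kinds at 1 h correlated at r = 0.57 across genes. As a mean over their clones Pik3ip1 stood at -0.23 and Mmp13 at 0.63, and without failed spots Ptk7 stood at 0.56, none of which passed. Nor did Dusp1 pass with no filter on dim spots, at 0.48.

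At 1 h 7 lists passed with the preset correlation. Of 23 immediate early genes 2 rose, and 7 adjusted over the list alone (camera adjusted p = 0.00659). Junb stood at 1.00 ± 0.33 (n = 3, fitted log2 1.05, adjusted p = 0.176) and Ier3 at 1.00 ± 0.58 (adjusted p = 0.176). Of 20 MAPK feedback genes 1, Dusp1 (0.86 ± 0.20), rose, and 5 adjusted over the list alone (camera adjusted p = 0.000297). Rgs2, a regulator of G protein signalling, stood at 1.28 ± 0.52 (n = 3, fitted log2 1.16, adjusted p = 0.123). Gadd45g stood at 1.08 ± 0.98 and Errfi1 at 0.54 ± 0.32. Of 20 oxidative stress genes 1, Mt2, rose, and 4 adjusted over the list alone (camera adjusted p = 0.00205), with Hmox1 at 1.76 ± 0.78 (adjusted p = 0.0612), Osgin1 at 1.28 ± 1.02 and the thioredoxin gene Txn1 at 0.67 ± 0.54. The heat shock list passed as a whole (camera adjusted p = 0.00659), with 1 of its 18 genes higher adjusted over the list alone and none over all genes by limma, as Hspa1a stood at 0.97 ± 0.57, Dnajb4 at 0.38 ± 0.33, Bag3 at 0.38 ± 0.53 and Chordc1 at 0.33 ± 0.60. With an estimated correlation, these 4 lists each gave an adjusted p = 0.117. In their order above the estimate was -0.026, -0.026, -0.028 and -0.0088, below the preset 0.01, so a larger correlation between genes was not the reason.

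Sik1, a CREB-induced kinase gene, rose by 0.95 ± 0.24 as 1 of 15 CREB, calcium and NFAT targets, of which 2 rose adjusted over the list alone (camera adjusted p = 0.00659, and an adjusted p = 0.171 with an estimated correlation). Crem (0.79 ± 0.31), Rcan1 (0.42 ± 0.16) and Rrad (0.41 ± 0.13) did not pass. YAP/TAZ targets lay below the other genes (camera adjusted p = 0.0437, and an adjusted p = 0.171 with an estimated correlation), with a positive ratio in 2 of 14 genes, a median log2 of -0.22, and 1 higher and 4 lower adjusted over the list alone. Amotl2 (-0.61 ± 0.24), Lats2 (-0.54 ± 0.23), Ccn1 (-0.93 ± 0.42, n = 3, fitted log2 -1.02, adjusted p = 0.194) and Tgfb2 (0.57 ± 0.38) did not pass over all genes. The 32 ribosomal protein genes, with 26 ratios above 0 and a median of 0.26, passed with the preset correlation (camera adjusted p = 0.000297) but not with an estimated one (adjusted p = 0.380). Of these, 1 rose adjusted over the list alone, and Rpl5 (0.58 ± 0.06), Rps14 (0.55 ± 0.60), Rpsa (0.47 ± 0.68) and Rps4x (0.42 ± 0.47) did not pass over all genes. With an estimated correlation, at -0.026 for YAP/TAZ and 0.045 for CREB targets, 0 lists passed at 1 h, the unadjusted counts of genes being those given above. By fry 7 passed, with matrix genes (fry adjusted p = 0.0130) in place of ribosomal proteins (fry adjusted p = 0.150). Without replicate 2 of 1 h 1 list passed, that of ribosomal proteins, with adjusted p-values of 0.0555 for MAPK feedback, 0.106 for the immediate early, oxidative stress and YAP/TAZ lists, 0.225 for heat shock and 0.236 for CREB targets. Without replicate 3 of 1 h 3 lists passed, with 0.0861 for immediate early genes, 0.0909 for heat shock, 0.0911 for YAP/TAZ targets and 0.121 for CREB targets. YAP/TAZ targets, which passed under 16 of 24 other settings, also stood at 0.0659 without replicate 1 of 1 h and at 0.141 without failed spots. Without spots that the software did not find, CREB targets stood at 0.192 and YAP/TAZ targets at 0.0565. With spots above background in both channels on all arrays they stood at 0.0837 and 0.0561, and CREB targets stood at 0.0566 with pairs of opposite dye averaged. Without both low-background arrays 4 lists passed, with CREB and YAP/TAZ targets at 0.0679 and heat shock at 0.0711. Under median centring, which moved the median of all genes to -0.14 at 1 h, the ribosomal list stood at 0.0620, YAP/TAZ targets at 0.0797 and heat shock at 0.129.

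The remaining lists did not pass at 1 h. Matrix genes came nearest (adjusted p = 0.0508), with Mmp13 the 1 called of 22 and 2 adjusted over the list alone. Hypoxia and glycolysis genes gave an adjusted p of 0.0842, actin cytoskeleton genes of 0.122, the cell cycle list of 0.182, macrophage markers of 0.282, the unfolded protein response of 0.305, cytokines of 0.322 and the circadian clock of 0.434. Wnt, osteoblast and endothelial lists stood at 0.910, growth factors at 0.703, muscle markers at 0.891, BMP and mechanosensing lists at 0.925, and the prostaglandin, interferon, cholesterol and chondrocyte lists at 0.791. Smad6 was the 1 called gene of the BMP list, in which 2 genes were higher and 2 lower adjusted over the list alone. The signs of median, mean and test differed for the osteoblast, BMP, mechanosensing, cholesterol and endothelial lists. Among the genes chosen for the topic, Ptgs2 stood at 0.16 ± 0.43, Fos at -0.02 ± 0.27, Egr1 at -0.32 ± 0.16, Ccn2 at -0.38 ± 1.05, Spp1 at 0.09 ± 0.17, Col1a1 at 0.20 ± 0.35, Actb at 0.14 ± 0.40 and Gapdh at 0.65 ± 0.57 (adjusted p = 0.194). Under median centring, Ptgs2 (-0.06), Spp1 (-0.13), Col1a1 (-0.01) and Actb (-0.11) lay below 0, as did Spp1 (-0.05) and Actb (-0.03) with the scanner's log ratio.

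**Figure D2:**
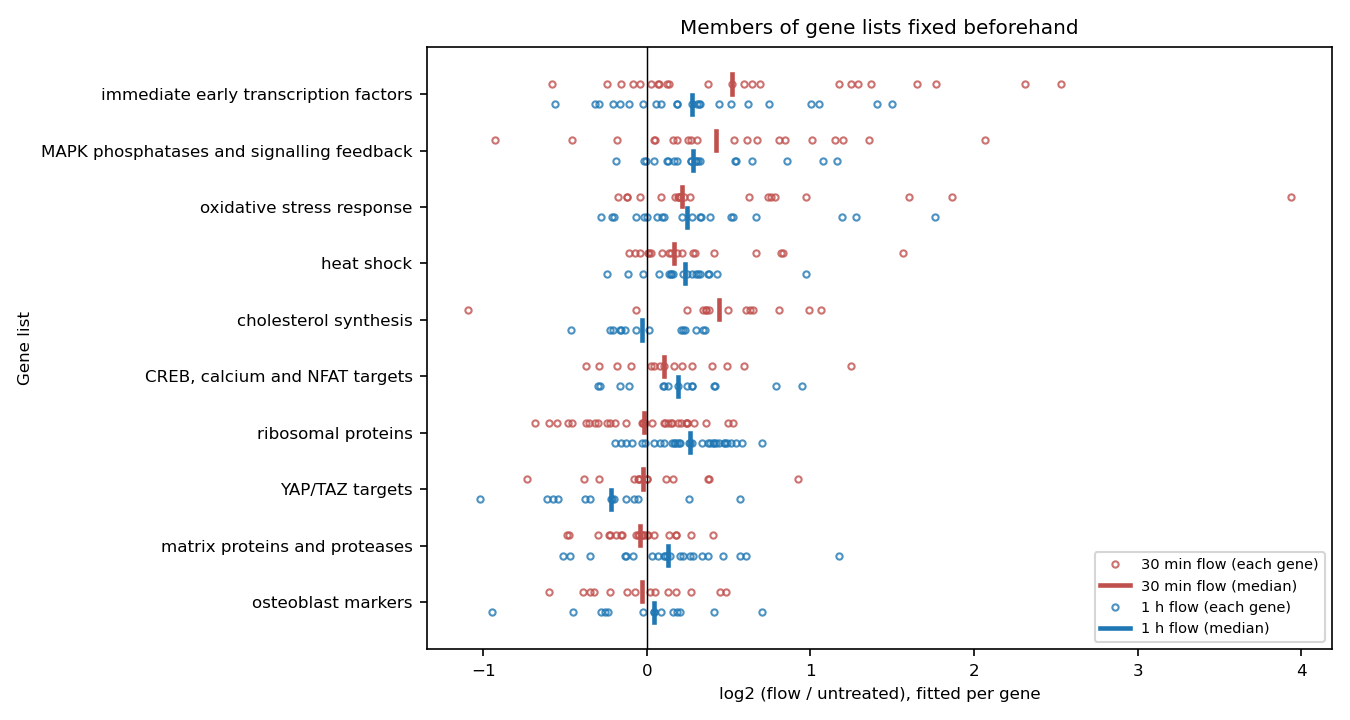
Fitted log2 ratio of flow over untreated (horizontal axis) of each measured gene (circles) in 10 gene lists, with the median (bars), at 30 min and 1 h. The median of the cholesterol synthesis list lies at 0.44 at 30 min and at -0.03 at 1 h, that of the ribosomal protein list at -0.02 and 0.26.

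The difference between the times was tested directly. The genes with the smallest p were Tnfrsf19, a TNF receptor family gene (1 h minus 30 min, log2 1.39), Socs3 (1.47), Igfbp4 (1.26), Igfbp5 (1.40) and Bach1, a haem-binding transcriptional repressor (1.05), which were higher at 1 h, and Plk2 (-1.55), Id2 (-1.39), Nr4a1 (-1.41), Tob2 (-1.19) and Klf10 (-1.39), which were lower. None passed, with adjusted p-values from 0.136 to 0.172 and n = 4 arrays per time. Limma called 0 of 8887 genes, with 776 at an unadjusted p under 0.05, and the unmoderated test per gene called 1. Without replicate 1 of 1 h, 5 genes passed, all lower at 1 h.

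As groups, 5 lists differed between the times with the preset correlation and 0 did with an estimated one, while fry called 4. Fry left out ribosomal proteins (fry adjusted p = 0.237) and the cell cycle (0.0645) and added oxidative stress (0.0309). The immediate early list was lower at 1 h than at 30 min (median difference -0.24, camera adjusted p = 0.00536; adjusted p = 0.159 with an estimated correlation), with 4 of 23 genes lower adjusted over the list alone, among them Nr4a1, Klf10, Csrnp1 (-1.12) and Fosl1 (-1.02). The cholesterol synthesis list was also lower (median -0.46, camera adjusted p = 0.000463; adjusted p = 0.159 with an estimated correlation), with Insig1 at -0.84, Idi1 at -0.84, Sqle at -0.83 and Msmo1 at -0.58. The cell cycle list was lower (median -0.16, camera adjusted p = 0.0381; adjusted p = 0.199 with an estimated correlation), with Rrm2 at -0.69, Aurkb at -0.68, Ccne2 at -0.65 and Mcm6 at -0.43. The ribosomal protein list was higher at 1 h (median 0.29, camera adjusted p = 0.000262; adjusted p = 0.402 with an estimated correlation), with 4 of 32 genes higher adjusted over the list alone, and with Rps4x at 0.88, Rplp1 at 0.85 and Rps6 at 0.74. The matrix list was higher (median 0.10, camera adjusted p = 0.0104; adjusted p = 0.159 with an estimated correlation), with Mmp13 at 1.19, Mmp2 at 0.62, Col3a1 at 0.56 and Dcn at 0.42. None of these genes passed over all genes. The estimated correlation was -0.026 for the immediate early, -0.00078 for the cell cycle and -0.032 for the matrix list, so a larger correlation was not why these 3 failed. It was 0.033 for cholesterol synthesis and 0.235 for ribosomal proteins. Of the lists that did not pass, the actin, cytokine, osteoblast, heat shock, mechanosensing, chondrocyte and endothelial lists differed in sign between median, mean and test. Under median centring the ribosomal list stood at an adjusted p of 0.146 and the matrix list at 0.200. The matrix list stood at 0.137 with the scanner's log ratio, and the cell cycle list at 0.0514 without the dye term and at 0.0547 with 1 h from its 2 low-background arrays. Without replicate 2 of 30 min 3 lists passed, with the matrix list at 0.0525 and the cell cycle list at 0.107. Without both low-background arrays 3 lists passed too, with the matrix list at 0.111 and the cell cycle list at 0.0617. Without replicate 2 of 1 h the matrix list stood at 0.0957, and the cell cycle list at 0.0725 without replicate 1 of 30 min, 0.0837 without replicate 1 of 1 h and 0.0599 without replicate 4 of 1 h.

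The mean of both times asked what flow changed over all 8 arrays. The genes with the largest changes were again Hmox1 (log2 2.85, SE 0.20), Prl2a1 (2.43), Csrnp1 (1.97) and Atf3 (1.91), which were highest, and Pik3ip1 (-1.07), Zfp503 (-1.05) and Irs1 (-1.03), which were lowest. Genes that passed on the mean and at neither time, chosen after their values were seen, included Ier3, an immediate early survival gene (1.19, SE 0.18, adjusted p = 0.0246), Noct, a gene with a circadian rhythm (1.05, SE 0.17, adjusted p = 0.0300) and Ccl2, a monocyte chemokine (0.92, SE 0.12, adjusted p = 0.0118). Atf4, a transcription factor of the amino acid and unfolded protein stress response (0.76, SE 0.12), and Ppp1r15a, a phosphatase subunit that restores translation after stress (0.82, SE 0.11), did so too. In all 79 genes passed on the mean, 53 higher and 26 lower, with 1365 at an unadjusted p under 0.05, and 39 of them had passed at neither time. The sign was the same on all arrays for 57 of the 79. The number fell to 15 under median centring, to between 19 and 31 when any 1 array was left out (21, 27, 25 and 20 without replicates 1 to 4 of 30 min, and 31, 28, 28 and 19 without those of 1 h), and to 16 without both low-background arrays.

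The same 7 genes passed at both times in the same direction: Atf3, Csrnp1, Dusp1, Mt2 and Prl2a1 higher, Crebzf and Pik3ip1 lower. Independent lists of these sizes would share 0.0608 higher and 0.00506 lower genes. The 2 lists are not independent even without an effect of flow, since both tests use 1 spread estimate per gene from all arrays. A gene with a small spread thus passes more easily at both times, so these expected numbers are too low a baseline. With each time fitted to its own arrays, 0 genes passed at 1 h and 0 were shared. The fold changes of the 2 times correlated at r = 0.22 across 8887 genes, with a covariance of 0.0190. If a single untreated RNA had been shared by all arrays and held 50% of the residual variance, a simulation with no effect of flow gave r = 0.80, a covariance of 0.115 and 703 shared calls. These values lie far above the observed ones. A shared RNA would shift a gene alike on all arrays and so not enter the residual variance, which makes the 50% an arbitrary setting. The simulation therefore cannot tell how much of the overlap sharing could explain. The labels do not say whether untreated RNA was shared, so part of the overlap may come from it. Of the 51 genes called at 30 min, 38 had the same sign at 1 h, and 50 were nearer to 0 or of the other sign; in the direction of the 30 min change, their median was 1.18 at 30 min and 0.27 at 1 h. These genes were chosen on their 30 min values. Over all genes the median absolute log2 ratio was 0.16 at 30 min and 0.18 at 1 h. Without replicate 2 or 4 of 30 min, 2 genes and 1 gene were shared, and without any other single array 0 were.

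**Figure D3:**
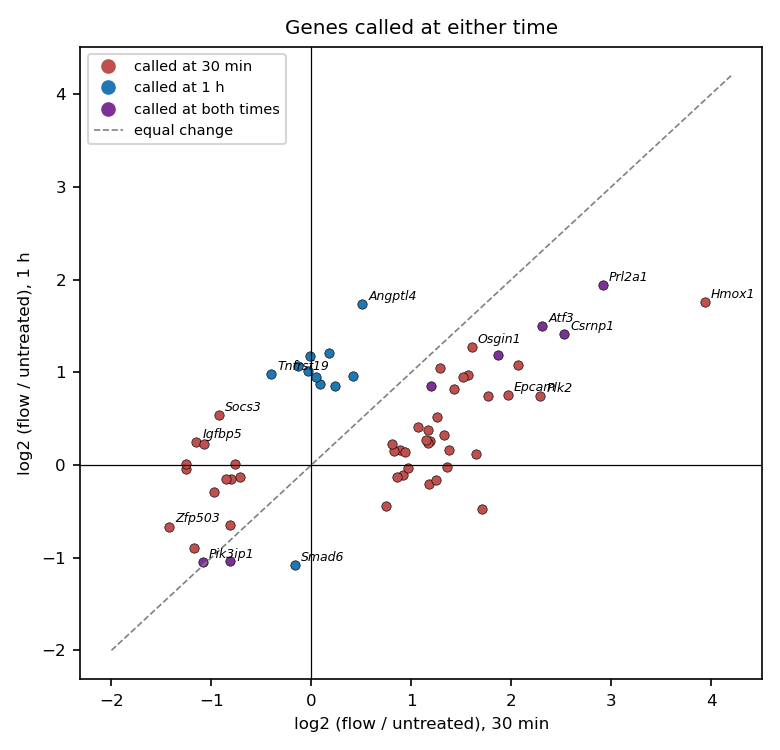
Fitted log2 ratio of flow over untreated at 30 min (horizontal axis) and 1 h (vertical axis) of the genes called at either time (points, coloured by the time of the call), with a dashed line of equal change. The 7 genes called at both times lie in the upper right and lower left, and 50 of the 51 genes called at 30 min lie nearer to 0 or on the other side of it at 1 h.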

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

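The tests of the immediate early list between times, of genes picked on 1 h arrays, of the clones and brightness of Fos and Egr1 and of the ribosomal list with an estimated correlation were chosen only after the results they bear on were seen, as was the separate dye term for both pairs of replicate numbers.

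Genes called at 30 min lay nearer to 0 at 1 h. Chance in picking them was tested with 50 genes picked on replicates 1 and 2 of 30 min. They averaged 1.24 on replicates 3 and 4 of 30 min and 0.495 at 1 h, a drop of 0.749 (95% interval over genes 0.581 to 0.918, 45 of 50 genes). On high-background arrays alone the drop was 0.778 (0.599 to 0.958, 43 of 50 genes), so it did not rest on the low red background alone. These intervals take genes as independent and hold no spread between arrays. If replicates 3 and 4 came from other extracts than replicates 1 and 2, the drop argues against chance in picking as the whole cause. The labels do not say whether they did. The same pick on replicates 1 and 2 of 1 h gave a drop in the other direction, from 0.990 on replicates 3 and 4 of 1 h to 0.673 at 30 min (0.317, 95% interval over genes 0.0506 to 0.583; 33 of 50 genes), so picking genes on a single time can account for part of the pattern, and larger changes at 30 min over all genes were not shown. A fading response with time remains a hypothesis: the immediate early list was lower at 1 h at an adjusted p = 0.00536 with the preset correlation but at 0.159 with an estimated one. Time and any batch of arrays of a time cannot be told apart, since no batch is named.

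Fos and Egr1 showed no rise at 30 min while other immediate early genes rose. A single bad clone is argued against, since all 7 clones of both genes gave log2 ratios of -0.15 or lower, and the highest upper 95% limit was 0.449. Too dim or saturated a signal is argued against as well: the dimmer of the 2 tested clones lay at percentile 63.9 of intensity, with 0 saturated spots. Cross-hybridization of the cDNA clones stays open, because none of the 7 clones had a sequence to search. A peak of these genes that had passed before 30 min may be a biological explanation and was not tested, as no earlier time was measured.

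For the ribosomal protein list, higher at 1 h, an intensity-dependent dye or background bias was tested with 10000 random lists matched on intensity. Their own median was -0.0218, so genes of like intensity were not shifted as a whole. The list's median of 0.262 lay at percentile 100 among them. Loess had already taken intensity trends out of each array, and genes picked at random vary together less than this list. The percentile therefore does not decide on a dye or background bias of these genes. The genes of the list vary together between arrays (correlation 0.235), and with that the adjusted p was 0.380, which is consistent with shared variation between arrays in place of flow. The median of the list followed the dye orientation, at -0.19, 0.22, -0.84 and 0.29 on replicates 1 to 4 of 30 min and at 0.14, 0.40, -0.25 and 0.86 on those of 1 h. A dye bias alike on both arrays of a pair of opposite orientation cancels in their average, which was 0.27 for replicates 1 and 2 and 0.30 for replicates 3 and 4 of 1 h. At 30 min, where the list did not pass, the same averages were 0.02 and -0.28. A pair average of such a size thus arose with either sign, so the like averages at 1 h do not settle the question. Variation between arrays that does not follow the dye stays open, and no biological explanation was tested beyond the time itself.

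Other sign patterns or splits of the arrays were counted for each number of calls. At 30 min and at 1 h, 8 patterns of 4 arrays are too few for a share under 0.05; the real pattern was the 1 with as many calls, at 51 against 0 for the highest other at 30 min, and again the 1 at 1 h with 18 against 16. For the difference between times the real count was 0 by limma (776 genes at an unadjusted p under 0.05, and 1 by the unmoderated test per gene), which all 34 of 34 splits reach by construction, so the share tests nothing; the highest gave 587. That split set replicates 1 and 4 of both times against 2 and 3, so it points to a structure of the samples, a dye bias that differed between replicates 1 and 2 and replicates 3 and 4. Replicates 1 and 2 correlated across genes at r = -0.24 at 30 min but at 0.59 at 1 h, where both had a low red background. Replicates 3 and 4 correlated at -0.39 and -0.54. The dye bias may thus also have differed between the times. On the mean of both times 2 of 99 patterns, the real one included, gave as many as 79. The other, at 127, turned replicates 2 and 3 and so followed the same structure, and with arrays that share a structure the patterns are not exchangeable, so the share does not settle whether chance can be excluded. With a separate dye term for each of these pairs of numbers, 115 genes passed at 30 min, 70 at 1 h, 0 for the difference and 363 on the mean.

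The value of Col1a1 on replicate 4 of 1 h, -0.31, lay far from the other 3 arrays of its time, at 0.33 to 0.44; chance marks about 1 in 20 such groups. All arrays of 30 min and all arrays of 1 h went opposite ways for Tnfrsf19 (1 h minus 30 min 1.39), Socs3 (1.47), Id2 (-1.39) and Tob2 (-1.19), each at an adjusted p of 0.136 for the difference, and for Rplp1 (0.85, adjusted p = 0.332), none of which passed. The effects on 5 gene lists differed between the times by the camera test of the difference, with median log2 differences of -0.239 for immediate early genes, 0.102 for matrix genes, -0.157 for the cell cycle, -0.465 for cholesterol synthesis and 0.292 for ribosomal proteins, and none with an estimated correlation. In data outside the comparisons of named genes, 8 cDNA clones without a gene symbol were called at 30 min or 1 h. Of 2095 spots of unknown clone identity, 6 were called, 4 higher and 2 lower.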

How the results depend on the processing

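The alternatives chosen only after the data were seen were those on the low-background arrays, on spots not found, on failed spots and on separate dye terms. Among values of 125 named gene comparisons over up to 32 alternatives, 3268 kept their side of the threshold and direction, 597 fell below the threshold, 51 rose past it, 16 values of genes that were not called changed sign and no called value reversed; Hmox1 at 30 min ranged from 2.27 to 4.59 in log2 units, with an adjusted p of up to 0.390. The count of 30 min genes, 51, became 28 with the scanner's log ratio, 12 with median centring, 162 with spots above background in both channels on all arrays, 24 without the dye term, 83 with trend and robust eBayes, 17 with pairs of opposite dye averaged, 118 at an adjusted p under 0.10, 0 by the unmoderated test per gene, 115 with separate dye terms for both pairs of replicate numbers, 114 without spots not found and 24 with 1 h from its 2 low-background arrays. The count of 1 h genes, 18, became 2 without background correction, 7 with an offset of 16, 0 with the scanner's log ratio, 0 with median centring, 99 with the strict filter, 4 with each clone on its own, 0 without the dye term, 0 with the arrays of its own time, 0 with averaged pairs, 35 at an adjusted p under 0.10, 1 by the unmoderated test, 70 with separate dye terms, 46 without spots not found, 0 with the 6 high-background arrays and 0 with the 2 low-background ones. For the difference, 0, the strict filter gave 28, the mean of clones 1, the unmoderated test 1 and the 6 high-background arrays 3. The count on the mean, 79, became 44 without background correction, 14 with the scanner's log ratio, 15 with median centring, 348 with the strict filter, 17 without the dye term, 171 with trend and robust eBayes, 18 with averaged pairs, 265 at an adjusted p under 0.10, 26 by the unmoderated test, 125 with a separate dye term for the low-background arrays, 363 with separate terms for both pairs, 214 without spots not found, 16 with the 6 high-background arrays and 9 with 1 h from the 2 low-background ones. The overlap of 7 genes became 2 without background correction, 4 with an offset of 16, 0 with the scanner's log ratio, median centring, no dye term, the arrays of each time alone, averaged pairs, the unmoderated test and either choice of arrays by background, 4 without a filter on dim spots, 16 with the strict filter, 2 with each clone on its own, 18 with separate dye terms and 13 without spots not found. The list counts became 3 of 5 at 30 min with the strict filter, 4 of 7 at 1 h with median centring and with the 6 high-background arrays, 3 of 5 for the difference with those 6 arrays, and 0 at 1 h and 0 for the difference with an estimated correlation. The strict filter tests fewer genes, the other filters on arrays use fewer samples, and the remaining causes were not tested.

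Leaving out 1 array at a time gave 7 to 37 genes at 30 min, 0 to 4 at 1 h, 0 to 5 for the difference, 19 to 31 on the mean and 0 to 2 in the overlap, and 1 to 10 lists at 1 h and 3 to 6 for the difference. With the replicate number as a block the counts were 60 at 30 min, 0 at 1 h, 0 for the difference, 134 on the mean and 0 in the overlap. Whether the numbers pair the samples was not settled. Same-numbered deviations correlated at 0.06, 0.05, 0.77 and 0.77, and at 0.22, -0.13, 0.24 and 0.24 after the dye term. Of the 30 min samples, 2 correlated best with their own number, and the block also holds the dye orientation. Median centring moved the median of all genes to -0.14 at 1 h and -0.21 for the difference, and the scanner's log ratio to -0.11 and -0.16. A block for slide or scan batch and the authors' value table were not run, since the files name no batch and the table holds no ratio. Signal over background limits the red channel most, with net values at or below 0 on 28.4 to 41.0% of spots of 6 arrays.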

Other observations

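The list of FOXO targets and the genes singled out here were chosen after the called genes were seen, and the test of that list was written before its result.

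Some called genes encode known regulators of the haem oxygenase gene or of the aryl hydrocarbon receptor. Mafk, a small Maf partner that binds the antioxidant element of such genes, rose at 30 min (log2 1.52 ± 0.81, n = 4, adjusted p = 0.0216), and Bach1, the repressor that pairs with small Maf proteins at that element, rose at 1 h (1.01 ± 0.17, adjusted p = 0.0279) with a value of -0.04 at 30 min. Tiparp, a target of the aryl hydrocarbon receptor that limits the receptor's activity, rose at 30 min (1.17 ± 0.28, adjusted p = 0.00697), with 0.81 on another clone, at the time at which Ahr itself fell (-1.26 ± 0.18). Tnfrsf19 rose at 1 h (0.98 ± 0.26, adjusted p = 0.0465), with -0.40 at 30 min. Under other settings the 1 h call was lost in 20 of 32 for Bach1 and in 23 of 32 for Tnfrsf19. The 30 min call was lost in 8 of 30 for Mafk, 6 of 32 for Tiparp and 5 of 32 for Ahr.

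Clones spotted more than once gave a measure of error within arrays. For 498 such clones the median gap between spots in mean log2 ratio at 30 min was 0.165, and 11 had a gap over 1. The widest was that of a clone without a symbol, at -1.26 and 3.49, followed by Sgce at -0.08 and 2.90 and by Fdft1 at -2.07 and -0.12. Dim spots that did not pass the filter do not show in these gaps. With them, the tested clones of Plk2, Epcam and Dusp1 stood at 1.14, 0.99 and 0.60 at 30 min.

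Pik3ip1 and Irs1, lower with flow at 30 min, are known targets of FOXO transcription factors, so it was asked whether FOXO targets fell as a group, which might follow from more PI3-kinase signalling. A list of 12 other measured targets, written without the called genes, gave an unadjusted p-value from camera in limma of 0.399 at 30 min (median -0.07) and of 0.169 at 1 h (median -0.15), and none of its genes was called by limma over all genes. Txnip had the lowest value, -0.99 at 30 min (adjusted p = 0.105) and -0.65 at 1 h (adjusted p = 0.293). The hypothesis was not borne out by this list.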
